A study of Homo sapiens
Mus musculus with 6 samples.

How the data were processed

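Gene expression was measured by RNA sequencing in 6 co-culture wells, each holding a mouse and a human cell line. The mouse cells were C2C12 myoblasts, a skeletal muscle precursor line, either as the control line or as a line stably carrying full-length Notch1. The human cells were HEK293-Flp-In embryonic kidney cells, either as the control line or carrying Jag1WT or Jag1Ndr, the product of the Nodder missense allele of Jag1. Per the labels, C2C12 cells settled for 8 h, were transfected with 1.6 ug per well of an empty plasmid, and received the HEK cells 18 h after transfection. The co-cultures were lysed after 6 h. The Notch1 line was kept under puromycin and the Jag1 lines under hygromycin, per the labels.

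PolyA RNA was made into libraries with a TruSeq kit that does not mark strand, per the labels. STAR and the builds mm9 and hg19 are named in the submitters' processing notes. The aligner's version, the counter and the way reads were told apart by species are not given in the sources used here. The authors deposited a mouse and a human table, each holding whole-number read counts per RefSeq gene and well, per the file headers. The same deposited tables hold RPKM, reads per kilobase of gene model and per 1000000 reads of that species, per the file headers. The deposited RPKM values were used for levels and for an alternative test, and the deposited counts for all main tests.

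The mouse table held 23905 entries, of which 472 exact repeats were left out, 93 repeated names were given a suffix and 121 names joined several genes. The human table held 24303 entries, with 448 exact repeats left out, 240 suffixed and 188 joined names. The columns were matched to wells by their titles. Gene reads per well ranged from 7637820 to 15496384 over both tables. Mouse reads ranged from 2263529 to 7965231 and human reads from 4081452 to 10292878, so the mouse table of the C2C12-Notch1 well with HEK-Jag1WT was the shallowest. Counting intervals and floors cover counting error only; the bootstrap and odds ratio intervals, named where given, are over genes.

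The groups were the 6 combinations of lines, with 1 well each. Each table was fitted separately with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr and the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The model was additive, with a term for the C2C12 line and a term for the HEK line, over all 6 wells, leaving 2 residual degrees of freedom. Wells sharing a line served as replicates, 3 per C2C12 line and 2 per HEK line. Any effect particular to 1 pair of lines therefore counted as spread. The labels name no separate cultures, so the p-values measure only the spread between these wells, which may be technical. The test covered 11365 mouse genes, with a common biological coefficient of variation of 3.89%, and 13596 human genes, with 3.48%.

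The lines compared, the models, the gene lists and the rule for named genes were fixed before the data were examined. Notch1 and Jag1 came first, in every well. Then up to 10 higher and 10 lower genes per comparison were taken by size of change, with an average log2 CPM of at least 2 and the same sign in every pair of wells differing only in the compared line. Up to 4 members per list by smallest p and all tested Notch target genes were added. Responses within 1 C2C12 line rest on single wells and were not tested. They are given as log2 ratios with a prior count of 2 and an exact conditional 95% counting interval, for genes with at least 100 reads in a well. Notch target genes are also given below that number of reads. The 95% counting interval of a list median comes from Poisson redraws of the reads of all its tested members. A fold against a group with 0 reads in all of its wells is a lower bound, computed against 3 reads over the group.

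The 19 gene lists covered Notch target genes, Notch receptors and ligands, Notch machinery, myogenic regulators, sarcomere genes, contractile and mural cell genes, matrix genes, TGF-beta and BMP response, immediate early genes, interferon response, NF-kB and cytokine genes, heat shock, unfolded protein response, p53 targets, hypoxia and glycolysis, cholesterol synthesis, cell cycle, C2C12 markers and HEK markers. Each was tested in 4 comparisons per species, 76 tests each. The set test was camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 76 tests of a species. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 of the mouse and 0 of the human list tests passed, with smallest adjusted p values of 0.815 and 0.613. At an unadjusted p under 0.05, that version of camera counted 1 and 2. In simulated data with 22 cell cycle genes raised 2-fold beside HEK-Jag1WT, it gave an unadjusted p of 0.00345 (mouse) and 0.00334 (human). Camera with the preset correlation gave 2.6e-53 and 5.31e-55 there. A clear change can thus give only a modest p with an estimated correlation, so not passing it is not by itself evidence against a list. The simulated genes varied independently of each other, so the simulation does not show why the real lists did not pass. Fry, which does not compare a list with other genes, passed 16 and 46. Medians of single-well responses were set against 10000 random lists of the same size matched on mean expression. The resulting percentiles cover neither variation between wells nor list members that move together.

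The pipeline was tested on simulated data drawn from the real means and library sizes. Apart from a small set of changed genes, each gene had the same mean in all wells, with the dispersion fitted to these wells. The simulated data thus held no effect of the other line or of a pair of lines. The shares below do not cover errors from such effects, or comparisons in which most genes differ. For HEK-Jag1WT against HEK-control in the mouse table, 88.1% of genes changed 2-fold were recovered among 11193 genes, and 82.1% of those changed 1.5-fold. False calls made up 6.32% of calls. For HEK-Jag1Ndr against HEK-control in the mouse table, the recovered shares were 85.1% and 68.7% among 11191 genes. False calls made up 5.59%. In the human table, 92.5% of 2-fold and 79.1% of 1.5-fold changes were recovered for the C2C12-Notch1 comparison among 13422 genes, with 6.77% false calls. For HEK-Jag1WT against HEK-control in the human table, 89.6% and 67.2% were recovered among 13405 genes, with 8.38% false calls, the highest share of the 8 simulated comparisons and above the 5% aimed at.

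The alternatives were DESeq2 size factors, scaling by library size only, limma-voom, limma on log2(RPKM + 1) and log2(RPKM + 0.1), no low-count filter, no term for the other line, glmTreat at 1.5-fold, the DESeq2 1.42.0 Wald test, other list tests, and leaving out each well in turn. Thinning all wells to the smallest total and leaving Jag1 out of the mouse table were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Genome coordinates were not used here, since the reference table is of another build than the files. Overlapping and antisense genes, and near-identical copies such as HSPA1A and HSPA1B, are uncertain, since the counting is not stated to use strand or to resolve copies. The values of 1 list member are not reported here.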

Results

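RNA was sequenced from 6 co-cultures in which mouse C2C12 cells received Notch ligand from human HEK cells for 6 h. Reads of the 2 species were counted in separate tables, so the response of the receiving mouse cells and the state of the sending human cells were read from the same wells. The C2C12-control line was placed with HEK-control, HEK-Jag1WT or HEK-Jag1Ndr, and the C2C12-Notch1 line likewise, with 1 well per combination. With HEK-control, HEK-Jag1WT and HEK-Jag1Ndr respectively, the C2C12-control wells held 3983213, 4613336 and 7965231 mouse reads and 4081452, 5150941 and 7142799 human reads. The C2C12-Notch1 wells held 5203506, 2263529 and 3845739 mouse reads and 10292878, 5374291 and 6683428 human reads. Mouse reads made up 49.8% ± 2.76 (SD, n = 3) of gene reads in the C2C12-control wells and 33.2% ± 3.45 (SD, n = 3) in the C2C12-Notch1 wells. The two-sided exact permutation p for this difference was 0.1, the smallest that 3 wells against 3 can give.

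The transgenes were read first. Mouse Notch1, the receptor gene, had 9.06, 20.4 and 12.7 RPKM in the C2C12-control wells with HEK-control, HEK-Jag1WT and HEK-Jag1Ndr, and 174, 179 and 158 RPKM in the matching C2C12-Notch1 wells. This was a log2 difference of 3.62 (SE 0.294, edgeR adjusted p 0.00859). Without the C2C12-control well with HEK-Jag1Ndr the adjusted p was 0.0797, the highest over all alternatives, and the log2 difference was 3.61. Reads on mouse Jag1, the ligand gene, followed the HEK line. They numbered 110 and 280 beside HEK-control, 42347 and 46762 beside HEK-Jag1WT, and 63416 and 63145 beside HEK-Jag1Ndr. Per 1000000 human reads, Jag1 stood at 27.1 ± 0.177 (SD, n = 2) in HEK-control wells, 8461 ± 339 in HEK-Jag1WT wells and 9163 ± 403 in HEK-Jag1Ndr wells, a ratio of 1.08 between the last pair. Human JAG1 had 8.33, 6.07 and 8.6 RPKM in the C2C12-control wells with HEK-control, HEK-Jag1WT and HEK-Jag1Ndr. In the matching C2C12-Notch1 wells it had 9.23, 5.16 and 10.2 RPKM, so it was lowest with HEK-Jag1WT beside both C2C12 lines. Human NOTCH1 had 7.87, 7.08 and 7.63 RPKM in the C2C12-control wells and 9.78, 8.33 and 8.11 RPKM in the C2C12-Notch1 wells, in the same order.

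**Figure D1:**
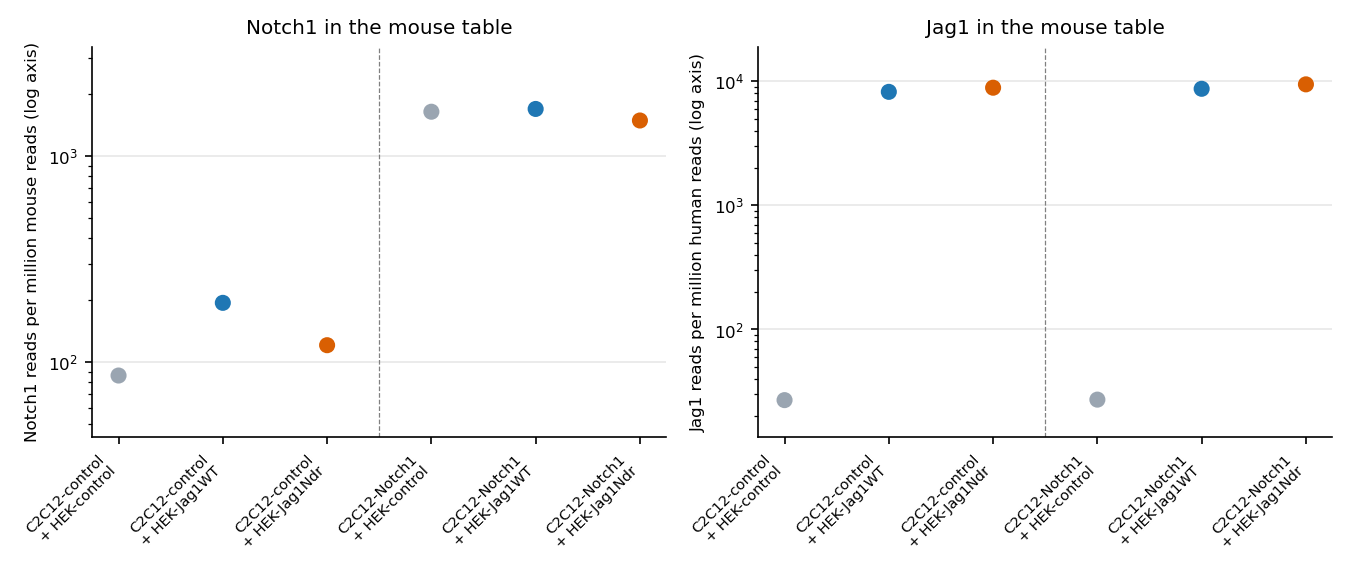
Notch1 reads per 1000000 mouse reads and mouse Jag1 reads per 1000000 human reads in each of the 6 co-culture wells, on log axes, with 1 point per well and colours for the HEK line. Mouse Notch1 is high in the 3 C2C12-Notch1 wells and mouse Jag1 in the 4 wells with a Jag1 line.

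Markers of each cell type were read in both tables, as the mean of each gene over the 6 wells. The median over the C2C12 marker list was 91.6 RPKM in the mouse table and 0.202 RPKM in the human table. The median over the HEK marker list was 45.2 RPKM in the human table and 0.0972 RPKM in the mouse table. Several HEK markers were exceptions. The neurofilament gene Nefl stood at 116 RPKM, Stmn2 at 62.7, Krt19 at 41.8 and Nefm at 41.1 in the mouse table, while STMN2 stood at 0.0185, NEFM at 0.618 and SALL4 at 0.0283 RPKM in the human table.

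The first comparison asked how C2C12-Notch1 cells differed from C2C12-control cells, across all HEK partners. Genes of the interferon response, the antiviral programme, were nearly silent in C2C12-Notch1 cells. All 19 tested members fell, with a median log2 change of -6.07 that stayed at -6.07 with Oas1a set to its bound. Bst2, which tethers budding virus, fell by 6.07 on the log2 scale, Oasl2 by a log2 change of -6.81 and Isg15, a ubiquitin-like modifier, by -5.38. Oas3, a sensor of double-stranded RNA outside the list, had no reads in these wells and was at least 634-fold lower. Sarcomere genes rose, 17 of 19, with a median of 1.45 and with Mylpf at 1.87, Acta1 at 1.31, Tnnc1 at 1.62 and Tnnt1 at 2.06. The interferon and sarcomere lists passed camera with adjusted p values of 4.02e-13 and 1.29e-06, and both had an adjusted p = 0.815 with an estimated correlation. Adjusted over the list alone, the counts were again 19 and 17.

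Among the genes with the largest changes, Ryr3, an intracellular calcium channel, rose by log2 5.62 (SE 0.307, edgeR adjusted p 2.43e-23). Gpr17 rose by 4.55, the cardiac transcription factor gene Nkx2-5 by 4.03 and the kinesin gene Kif1a by 3.72. The cadherin gene Cdh11 was at least 316-fold lower, the collectin gene Colec12 at least 225-fold lower and Trim44 at least 168-fold lower. Hypoxia and glycolysis genes fell in 12 of 14 cases and rose in 1, with a median of -0.96, Ndrg1 at -1.49, Pdk1 at -1.49 and Ldha at -0.71. NF-kB and cytokine genes fell in 8 of 13 cases and rose in 1, with Vcam1 at -1.41 and Ccl2 at -1.83. Targets of p53 rose in 11 of 13 cases and fell in 2, with Ccng1 at 0.66. Unfolded protein response genes rose in 14 of 18 cases and fell in 2, or in 3 adjusted over the list alone, with the chaperone gene Hspa5 at 0.74 and Trib3 at 1.37. These 4 lists had camera adjusted p values of 1e-04, 0.0249, 0.00771 and 0.00623, and each had an adjusted p = 0.815 with an estimated correlation.

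The Notch target list was not called as a whole in this comparison (median 0.33, camera adjusted p 0.274), with 5 of 10 genes higher and 2 lower, or 6 and 2 adjusted over the list alone. Nrarp, a feedback inhibitor of Notch, rose by log2 2.11 and the repressor gene Hey1 by 0.87, while Lfng, a modifier of Notch receptors, fell by 0.81 on the log2 scale. Contractile and mural cell genes were split, with 5 of 8 higher and 3 lower, Acta2 at 2.30, Tagln at 2.26 and the pericyte receptor gene Pdgfrb at -1.48. Myogenic regulators were higher in 7 of 10 cases and lower in 1, with Myod1 at 0.94, Myog at 1.48 and Pax7 at 2.08. Matrix genes went both ways, 9 higher and 8 lower of 21, with Col4a1 at 1.73, Col1a1 at -3.02 and the proteoglycan gene Bgn at -5.47. TGF-beta and BMP response genes were higher in 7 of 11 cases and lower in 2, and cell cycle genes lower in 14 of 22 and higher in 4. The other lists, none of them called by camera, gave counts of higher and lower genes of 4 and 8 of 25 for Notch machinery, 4 and 1 of 6 for Notch receptors and ligands, 2 and 7 of 14 for immediate early genes, and 2 and 3 of 9 for heat shock. The 6 Notch receptor and ligand genes include the introduced Notch1, and Jag1, whose reads come mostly from the HEK cells. Cholesterol synthesis had 3 and 4 of 16, C2C12 markers 5 and 7 of 13, and HEK markers 1 and 3 of 4. Adjusted over the list alone, immediate early genes had 3 and 7 and cholesterol synthesis 2 and 4, and the remaining counts of this comparison were the same.

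In all, edgeR called 6569 of 11365 mouse genes (57.8%) between the C2C12 lines, 3229 higher and 3340 lower, of which 372 and 788 changed more than 2-fold. The DESeq2 Wald test called 3585.

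The next question was how C2C12 cells responded to HEK-Jag1WT, the wild-type ligand, against HEK-control. Notch target genes rose within 6 h, 6 of the 10 tested, with a median log2 change of 0.89. Nrarp rose by log2 5.27 (SE 0.275, edgeR adjusted p 9.88e-23), from 12 reads in the HEK-control wells. Hey1 rose by 2.56 (SE 0.161, adjusted p 0.000156) and Notch3, a Notch receptor gene that is itself a target, by 0.95 (adjusted p 1.49e-08). The list passed camera (adjusted p 7.51e-06), with an adjusted p = 0.815 with an estimated correlation, and 7 genes were higher and 1 lower adjusted over the list alone. The other members were Gata3 at 0.82, Hes1 at 0.50, Hey2 at 2.35 and, not passing, Heyl at 3.41 (adjusted p 0.165), Myc at 0.06 and Lfng at -0.10. Ccnd1, the cyclin D1 gene, fell by 0.42 on the log2 scale.

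Outside the list, 8430408G22Rik rose by log2 3.86 (adjusted p 5.92e-24), the adhesion receptor gene Gpr133 by 2.59, Dio2, which activates thyroid hormone, by 2.14 and the corepressor gene Cbfa2t3 by 1.80. The muscle determination genes moved apart: Myf5 rose by 1.33 (adjusted p 1.83e-18) and Myod1 fell by 0.77 on the log2 scale (adjusted p 4.03e-09). Among contractile and mural cell genes Pdgfrb rose by 0.73 and Cspg4 by 0.45, 2 of 8, with the list at a median of 0.12 (camera adjusted p 0.0199). Notch receptors and ligands had 2 of 6 higher, Notch3 and the HEK-derived reads on Jag1 itself. That list had the same camera adjusted p of 0.0199 with Jag1 in it, and 0.409 without Jag1, so its call rested on the introduced gene. Counts adjusted over the list alone were the same, and each list had an adjusted p = 0.815 with an estimated correlation. Wnt7b, a Wnt ligand gene, fell by 1.19 on the log2 scale.

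TGF-beta and BMP response genes went both ways beside HEK-Jag1WT and were not called as a list (median 0.18, camera adjusted p 0.131), with 3 of 11 higher and 2 lower, or 4 and 2 adjusted over the list alone. Id3, a target of bone morphogenetic protein, rose by log2 0.93 and Tgfb1 by 0.53, while Skil stood at -0.28 (edgeR adjusted p 0.0162) and Ltbp2, named after its values were seen, at -0.32 (0.0296). The call of Skil was lost without the C2C12-control wells with HEK-control (0.157) or HEK-Jag1WT (0.439) or the C2C12-Notch1 well with HEK-Jag1WT (0.0515), in a range from 0.00476 to 1. That of Ltbp2 was lost without the C2C12-control (0.0658) or C2C12-Notch1 (0.125) well with HEK-control or the C2C12-Notch1 well with HEK-Jag1WT (0.406), in a range from 0.0075 to 1. Of the immediate early genes, also not called as a list (camera adjusted p 0.597), the phosphatase gene Dusp1 rose by 0.98, 1 of 14, or 2 higher and 1 lower adjusted over the list alone.

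In total, 507 of 11365 genes passed, Jag1 included, 307 higher and 200 lower, with 55 and 14 changed more than 2-fold; the higher share was 60.6%, and 47.1% of 531 calls when wells were scaled by library size only. DESeq2 called 151, of which 76.2% were higher. Without the C2C12-Notch1 well with HEK-Jag1WT 303 genes passed, and without the C2C12-control well with HEK-Jag1WT 320. The calls of Gata3 and Hes1 were lost without the C2C12-control well with HEK-control (edgeR adjusted p 0.0887 and 0.46) or with HEK-Jag1WT (0.111 and 0.643). Their adjusted p ranged over all alternatives from 0.00048 to 1 for Gata3 and from 7.08e-05 to 1 for Hes1. The call of Hey2, a gene with few reads, was lost without any of the wells with HEK-control or HEK-Jag1WT (adjusted p 0.115, 0.123, 0.314 and 0.352), in a range from 0.00462 to 1. The call of Cspg4 was lost without the C2C12-control well with HEK-control (0.267) or HEK-Jag1WT (0.122) and without the C2C12-Notch1 well with HEK-Jag1WT (0.199), in a range from 0.00672 to 1.

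The same question was asked of HEK-Jag1Ndr against HEK-control. The C2C12 response was small. Dio2 rose by log2 0.88 (edgeR adjusted p 2.4e-07), the differentiation inhibitor genes Id2 by 0.85 and Id3 by 0.82 (adjusted p 4.51e-08), and Sec14l2 by 0.68. Of the 10 Notch targets Nrarp passed, at 1.79 (SE 0.446, adjusted p 0.0395). Hey1 stood at 1.197 (adjusted p 0.0581), Heyl at 1.62 (0.749), Notch3 at 0.27 (0.191) and Hes1 at 0.30 (0.468). The Notch target list had a median of 0.28 and passed camera (adjusted p 0.000311), with 1 of 10 higher, or 4 higher and 1 lower adjusted over the list alone, and an adjusted p = 0.815 with an estimated correlation.

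TGF-beta and BMP response genes also passed camera beside HEK-Jag1Ndr (median 0.26, adjusted p 1.06e-05), with Id1, Id2 and Id3 higher of 11 members and 7 higher adjusted over the list alone. Immediate early genes passed with 1 of 14 higher, Dusp1 at 0.52, or 4 adjusted over the list alone (median 0.14, camera adjusted p 0.00303). Contractile and mural cell genes passed with 1 of 8, Pdgfrb at 0.27, also adjusted over the list alone (camera adjusted p 0.0465). All 3 lists had an adjusted p = 0.815 with an estimated correlation. The interferon list was not called (camera adjusted p 0.164), with 4 of 19 genes higher, Usp18, Ifit1, Ifit3 and Isg15, the last at 0.40, or 9 adjusted over the list alone. In C2C12-control cells, on single wells and not tested, the list median was log2 0.265, and 0.33 against HEK-Jag1WT. Both lay at percentile 100 among random lists matched on expression, which cover neither variation between wells nor members that move together. In C2C12-Notch1 cells the list median was 0, and a fit without a C2C12-control well can say little about the list. Its members are nearly absent from the C2C12-Notch1 wells, and the 4 calls and 3 of the 4 signs did not hold without 1 of the C2C12-control wells. Without the well with HEK-control, Usp18 turned to -1.44 and Ifit3 to -3.73, while Ifit1 stood at 1.49 and Isg15 at 0.41 (edgeR adjusted p 0.832, 0.649, 0.727 and 0.826). Without the well with HEK-Jag1Ndr, Usp18 turned to -4.18, Ifit3 to -3.27 and Isg15 to -0.19, and Ifit1 stood at 1.62 (0.74, 0.869, 0.984 and 0.791). Over all alternatives the adjusted p of Usp18, Ifit3, Ifit1 and Isg15 ranged from 0.000661, 0.000719, 0.00715 and 0.0019 to 1, and DESeq2 gave Usp18 a log2 change of -0.30.

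Here 60 of 11365 genes passed (0.528%), Jag1 included, 49 higher and 11 lower, with 3 changed more than 2-fold; 81.7% were higher, and 69.2% of 52 calls under library size only. The higher share also fell below 69.2% without the C2C12-control well with HEK-control or with HEK-Jag1Ndr, and stayed above it without any other well. DESeq2 called 6 genes. The call of Nrarp was lost without the C2C12-control well with HEK-Jag1Ndr (edgeR adjusted p 0.273), the C2C12-Notch1 well with HEK-control (0.805) or that with HEK-Jag1WT (0.0512), in a range from 0.0172 to 1 over all alternatives. Those of Id1 and Dusp1 were lost without the C2C12-Notch1 well with HEK-control (0.0646 and 0.0602), that of Id1 also without the C2C12-Notch1 well with HEK-Jag1Ndr (0.226), in ranges from 1.34e-08 and 3.37e-06 to 1. The call of Pdgfrb was lost without the C2C12-control well with HEK-control (0.572) or with HEK-Jag1Ndr (0.831), in a range from 0.0172 to 1.

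The ligands were then compared directly. Notch target genes were lower beside HEK-Jag1Ndr than beside HEK-Jag1WT, 4 of 10 with 1 higher, with a median log2 difference of -0.71. Nrarp was lower by a log2 difference of -3.48 (SE 0.215, edgeR adjusted p 5.23e-19), Hey1 by -1.36 (SE 0.138, adjusted p 0.00431) and Notch3 by -0.69 (adjusted p 5.78e-06). On single wells, Heyl stood at -2.019 (counting interval -2.131 to -1.915) in C2C12-control and -1.234 (-1.483 to -0.9987) in C2C12-Notch1 cells. A response that differs in size between the C2C12 lines counts as spread in the test. Myf5 was lower by -0.87 and Dio2 by -1.26, while Myod1 was higher by 0.81 (adjusted p 1.33e-09). The Notch target list passed camera (adjusted p 1.06e-05), with the same counts adjusted over the list alone and an adjusted p = 0.815 with an estimated correlation. Reads on Jag1 in the mouse table were lower by -0.28 (adjusted p 0.000108) on a scale set by mouse reads, a call lost without the C2C12-Notch1 well with HEK-Jag1WT (adjusted p 0.446, in a range from 4.96e-08 to 1).

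NF-kB and cytokine genes had 2 of 13 higher beside HEK-Jag1Ndr, the chemokine gene Cxcl5 at 1.77 and the macrophage growth factor gene Csf1 at 0.32, or 5 adjusted over the list alone (median 0.32, camera adjusted p 0.000525). Hypoxia and glycolysis genes had 2 of 14 lower, Pdk1 at -0.34 and Ndrg1 at -0.26, or 4 adjusted over the list alone (median -0.11, camera adjusted p 0.0465). Both lists had an adjusted p = 0.815 with an estimated correlation. In all, 231 genes passed, 78 higher and 153 lower, and DESeq2 called 41. The higher share, 33.8%, was smaller without the C2C12-control well with HEK-Jag1WT or with HEK-Jag1Ndr, and not without any other well. The call of Cxcl5 was lost without the C2C12-control well with HEK-Jag1WT (edgeR adjusted p 0.286, in a range from 9.08e-07 to 1). Those of Csf1, Pdk1 and Ndrg1 were lost without the C2C12-Notch1 well with HEK-Jag1WT (0.172, 0.412 and 0.792). That of Csf1 was also lost without the C2C12-control well with HEK-Jag1Ndr (0.0911), and those of Pdk1 and Ndrg1 without the C2C12-Notch1 well with HEK-Jag1Ndr (0.0788 and 0.406), in ranges from 0.000236, 0.000291 and 0.00306 to 1. Without the C2C12-Notch1 well with HEK-Jag1WT 138 genes passed, without the C2C12-control well with HEK-Jag1WT 141, and without the C2C12-Notch1 well with HEK-Jag1Ndr 150.

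Within each C2C12 line the responses rest on single wells and were not tested. In C2C12-control cells the median Notch target response was log2 1.04 to HEK-Jag1WT and 0.54 to HEK-Jag1Ndr. In C2C12-Notch1 cells it was 0.75 and 0.11. Among random lists matched on expression these medians lay at percentiles 100, 100, 100 and 96.3. The last median, 0.11, had a counting interval of 0.0165 to 0.315 from Poisson redraws, with members of few reads included, and was 0.0732 under library size only. Heyl, a Hey family repressor gene, went from 126 to 2325 reads with HEK-Jag1WT in C2C12-control cells, a log2 ratio of 3.999 (counting interval 3.76 to 4.29), and from 141 to 339 reads in C2C12-Notch1 cells, 2.497 (2.23 to 2.81). Hey1 had ratios of 2.99 (2.74 to 3.27) and 2.25 (2.09 to 2.43). Nrarp went from 2 to 75 reads in C2C12-control cells, a ratio of 4.18 (3.14 to 8.11), and from 10 to 174 in C2C12-Notch1 cells, 5.08 (4.46 to 6.46). Beside HEK-Jag1Ndr, Heyl had ratios of 1.98 and 1.26 and Hey1 of 1.41 and 1.14 in the C2C12-control and C2C12-Notch1 lines.

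**Figure D2:**
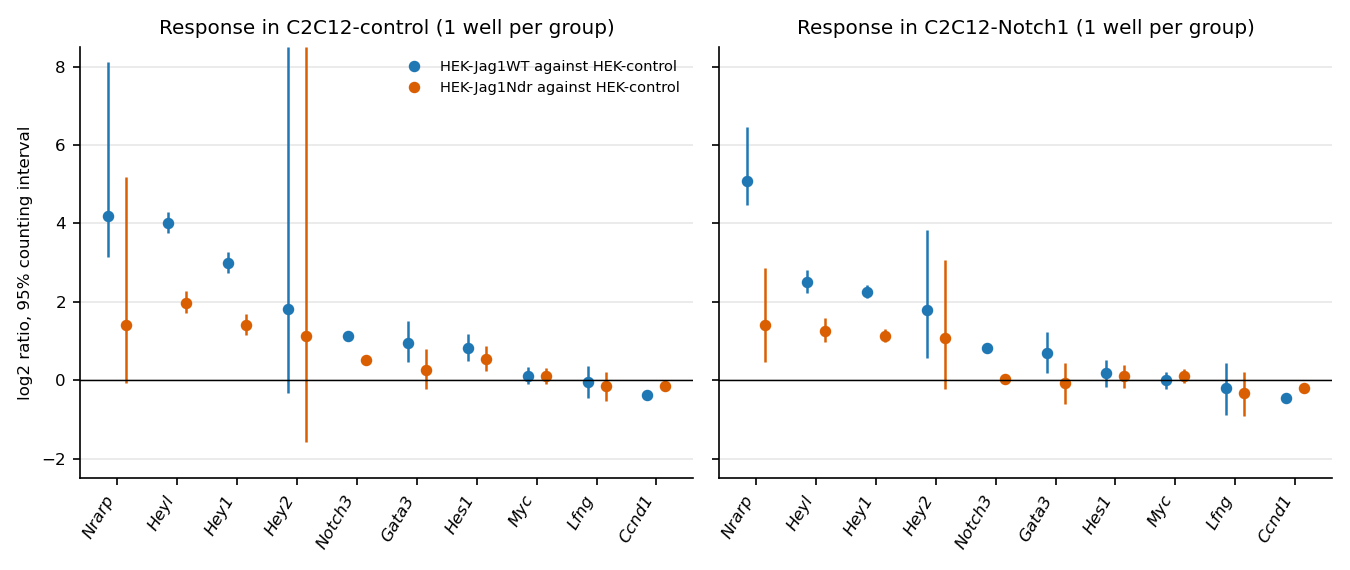
Log2 ratio of Notch target genes beside each Jag1 line against HEK-control, in each C2C12 line, 1 point per gene and well pair with its 95% counting interval. The median was 1.04 beside HEK-Jag1WT and 0.54 beside HEK-Jag1Ndr in C2C12-control cells; the Hey2 intervals of that line have no upper end and stop at the top of the axis.

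Genes chosen for a HEK-Jag1WT response of at least 2-fold in one C2C12 line were read in the other, so that choice and reading used different wells. The 28 genes chosen as higher in C2C12-control cells had, in C2C12-Notch1 cells, a median HEK-Jag1Ndr response that was 30.8% of the HEK-Jag1WT response (bootstrap interval over genes 22.6 to 47.3). These 28 include Notch1, whose reads in C2C12-Notch1 cells include the introduced gene. The 29 genes chosen in C2C12-Notch1 cells gave 47.7% (37.8 to 58.9) in C2C12-control cells. For lower genes the shares were less certain. The 3 chosen in C2C12-control cells, Ptpn22, Car8 and Sema3c, gave 42.9% (16.8 to 81.7), and the 10 chosen in C2C12-Notch1 cells gave 34.4% (-76.6 to 85), with 7 of the 10 also lower beside HEK-Jag1Ndr. The collagen genes Col6a1 and Col6a2 responded more to HEK-Jag1WT in C2C12-Notch1 than in C2C12-control cells, at log2 2.32 against 1.15 and 2.77 against 1.46. The hyaluronan synthase gene Has2 stood at 1.90 against 0.99. Heyl and 8430408G22Rik responded less in C2C12-Notch1 cells, with differences of -1.502 and -1.26. The higher Jag1 reads per mouse read in the C2C12-Notch1 wells cannot be told apart from Notch1 in these differences between the lines.

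Leaving Jag1 out, 40 of the 48 mouse genes higher beside HEK-Jag1Ndr were also higher beside HEK-Jag1WT, where independent lists would share 1.29, and all 11 lower genes were shared, against 0.194. No called gene went opposite ways. Unchanged groups simulated against the same HEK-control wells shared 0 calls. That value leaves out the effects and the value for independent lists leaves out the shared wells, so part of the excess may come from the shared wells. Across genes the log2 changes correlated with r = 0.611 and a covariance of 0.0366, against 0.496 and 0.0187 in 10 simulations, and genes are not independent replicates. With the pair of responses taken from different C2C12 lines, r was 0.238 and 0.253, and the rank correlation 0.158 and 0.106.

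**Figure D3:**
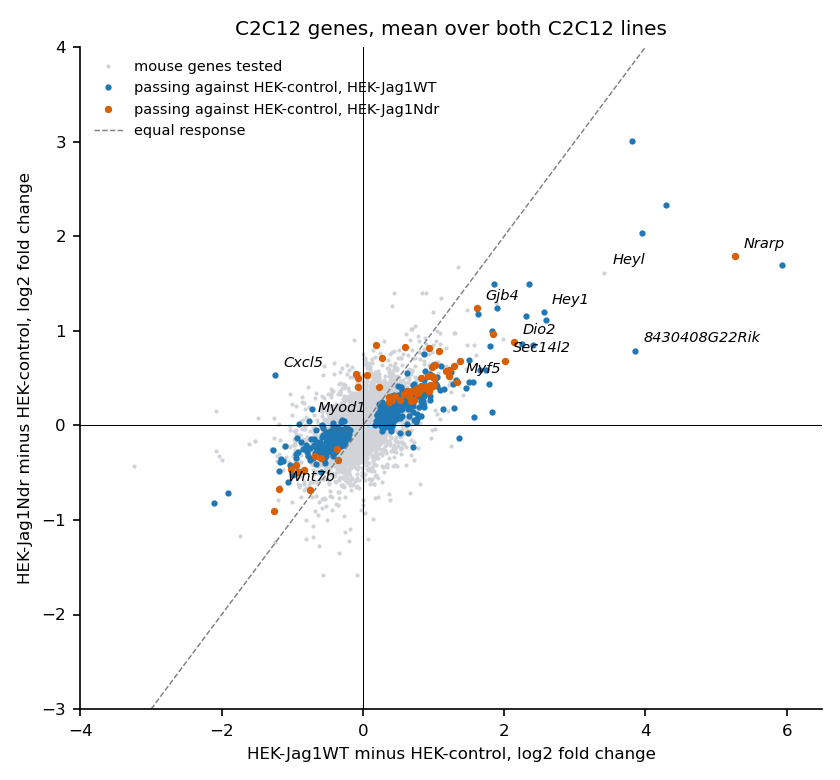
Log2 change of mouse genes beside HEK-Jag1Ndr against log2 change beside HEK-Jag1WT, each relative to HEK-control, 1 point per tested gene, Jag1 left out; coloured points passed edgeR in a comparison and the dashed line marks equal responses. Nrarp lies at 5.27 on the HEK-Jag1WT axis and 1.79 on the HEK-Jag1Ndr axis.

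The human table was used to ask whether the HEK cells differed with their C2C12 partner. Beside C2C12-Notch1, interferon response genes of the HEK cells rose, 9 of 15, with a median of log2 0.60. OASL, an antiviral gene, rose by 0.95 (SE 0.0423, edgeR adjusted p 1.58e-26), the RNA sensor genes DDX58 by 0.89 and IFIH1 by 0.83, and IFIT2 by 0.79. Immediate early genes rose in 8 of 14 cases, or 12 adjusted over the list alone, with EGR1 at 0.53, ATF3 at 0.57 and FOS at 0.56. Hypoxia and glycolysis genes fell in 6 of 13 cases, or 8 adjusted over the list alone, with the glucose transporter gene SLC2A1 at -0.60, EGLN3 at -0.71 and LDHA at -0.22. The lists passed camera with adjusted p values of 3.81e-08, 2.53e-08 and 0.000298, and all 3 had an adjusted p = 0.613 with an estimated correlation. Mouse reads made up 33.2% of gene reads in these wells against 49.8% in the others.

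**Figure D4:**
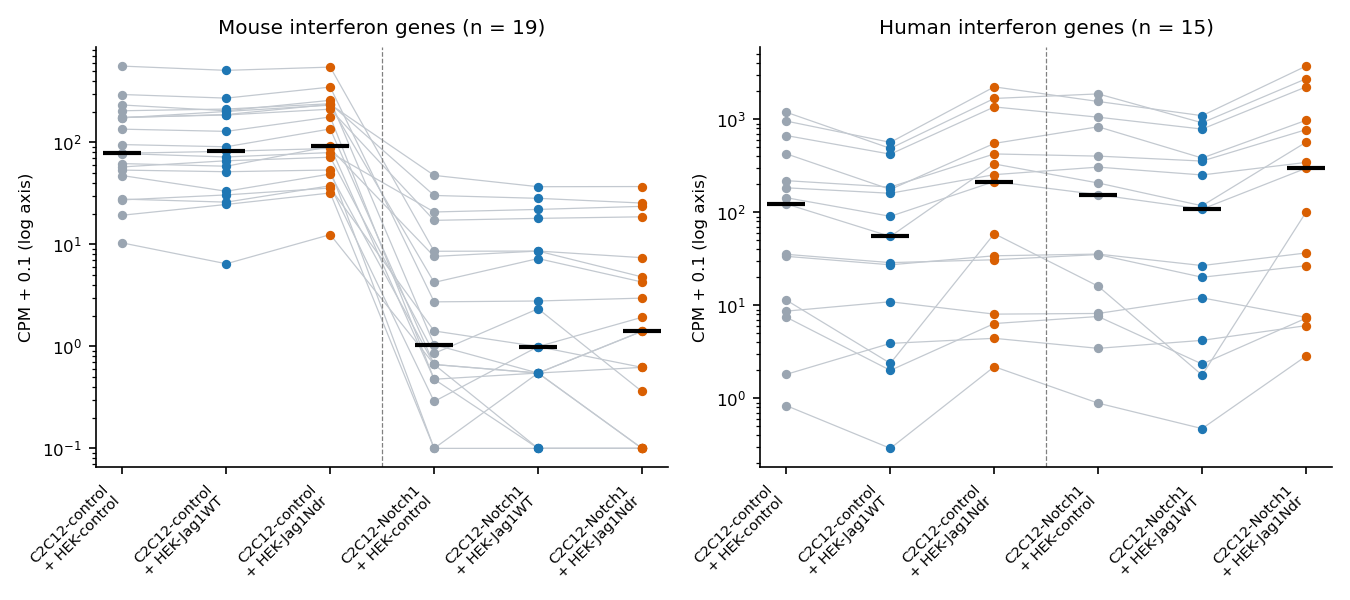
Interferon response genes in each well, mouse genes in one panel and human genes in the other, as CPM + 0.1 on a log axis; points are genes, lines join the same gene and black bars are medians. Mouse members are lower in the C2C12-Notch1 wells, with a median log2 change of -6.07, and human members are higher there, with a median of 0.60.

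ID1 rose by log2 1.03 (edgeR adjusted p 1.12e-05), the prostaglandin synthase gene PTGS2 by 0.83 and the matricellular gene CYR61 by 0.55, and the glucose transporter gene SLC2A3 fell by 0.81 on the log2 scale. HLA-L, an HLA pseudogene, was lower by a log2 difference of -2.26 and HNRNPA3P1, a pseudogene, by -0.89; reads of such copies are uncertain. In all 658 of 13596 human genes passed, 417 higher and 241 lower, with 1 and 12 changed more than 2-fold. The higher share was 63.4%, and 41.8% of 603 calls under library size only, and DESeq2 called 71. The count moved with every well left out. It was 1413, 199 and 176 without the C2C12-control wells with HEK-control, HEK-Jag1WT and HEK-Jag1Ndr, and 1428, 200 and 178 without the matching C2C12-Notch1 wells.

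The HEK lines themselves were compared next. HEK-Jag1WT cells had lower p53 target, matrix and interferon genes and higher cell cycle genes than HEK-control cells. Targets of p53 were lower in 10 of 13 cases, with the receptor gene EDA2R at a log2 change of -4.34, the stress gene SESN2 at -1.56 and GDF15 at -2.31. Matrix genes were lower in 13 of 17 cases and higher in 1, with fibronectin, FN1, at -1.59. Interferon response genes were lower in 12 of 15 cases and higher in 1, with IFIT1 at -1.15. Cell cycle genes were higher in 14 of 22 cases and lower in 1, with MKI67 at 0.79 and MCM7 at 0.66. These lists had camera adjusted p values of 0.000707, 0.00304, 0.0035 and 0.00485, the same counts adjusted over the list alone, and each an adjusted p = 0.613 with an estimated correlation. ANKRD1 was higher by 3.95, SERPINB9 by 3.76 and the zinc finger gene PLAGL1 by 3.14, and the ephrin receptor gene EPHA3 was at least 36.1-fold lower. In all 7379 genes passed, 3386 higher and 3993 lower, and DESeq2 called 4267.

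HEK-Jag1Ndr cells had higher interferon, matrix and immediate early genes than HEK-control cells. Interferon genes were higher in 11 of 15 cases and lower in 1, with IFIH1 at log2 1.45, IFIT2 at 1.25 and RSAD2 at 2.57. Matrix genes were higher in 12 of 17 cases and lower in 3, with FN1 at 1.07. Immediate early genes were higher in 9 of 14 cases and lower in 1, with the nuclear receptor gene NR4A1 at 1.54 and EGR1 at 0.96. Of the C2C12 markers, 4 had enough reads in the human table to be tested and 3 were higher, the matrix genes SPARC at 0.78, COL3A1 at 1.88 and COL1A1 at 0.49. The call of COL1A1 was lost without the C2C12-control wells with HEK-control (edgeR adjusted p 0.0851) or HEK-Jag1Ndr (0.111), in a range from 0.000923 to 1. The lists had camera adjusted p values of 0.00157, 0.00326, 0.0158 and 0.0469, the same counts adjusted over the list alone, and each an adjusted p = 0.613 with an estimated correlation. SERPINB2 was higher by 5.08, and ZNF91, a zinc finger repressor gene, at least 59.5-fold lower. In all 6266 genes passed, 3068 higher and 3198 lower, and DESeq2 called 2995.

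Between the Jag1 lines, HEK-Jag1Ndr had higher interferon genes in 12 of 15 cases with 1 lower, a median log2 difference of 1.48 and RSAD2 at 5.31. Matrix genes were higher in 13 of 17 cases with 2 lower, and FN1 at 2.66. Targets of p53 were higher in 11 of 13 cases with 1 lower, and EDA2R at 5.79. TGF-beta and BMP response genes were higher in 7 of 12 cases, with CTGF at 1.54 and ID1 at 2.18. These lists had camera adjusted p values of 4.46e-05, 0.00055, 0.0035 and 0.0228, the same counts adjusted over the list alone, and each an adjusted p = 0.613 with an estimated correlation. SERPINB9, a granzyme inhibitor gene, was at least 151-fold lower in HEK-Jag1Ndr. In all 7843 genes passed, 3966 higher and 3877 lower, and DESeq2 called 4866.

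**Figure D5:**
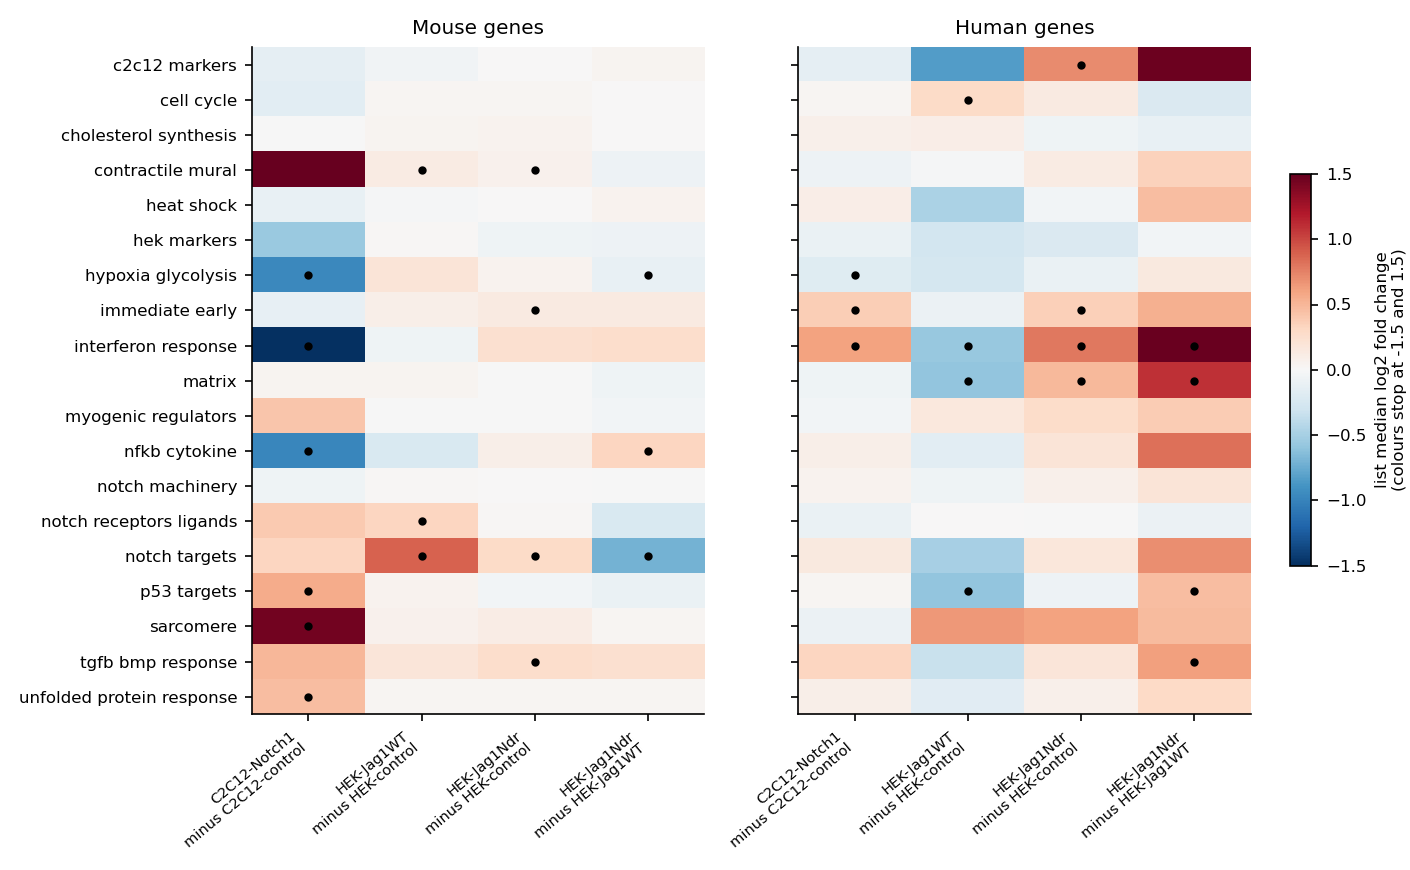
Median log2 change of each gene list in the 4 comparisons, for mouse and human genes; colours stop at -1.5 and 1.5, and dots mark a camera adjusted p under 0.05. The mouse interferon list stands at -6.07 between the C2C12 lines.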

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

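All tests on these patterns were chosen after the results were seen, except the share of mouse reads needed by the hypoxia genes and the counts over other splits of the wells.

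The first pattern is the higher interferon and immediate early genes and lower hypoxia genes of HEK cells beside C2C12-Notch1. Mouse reads counted as human are argued against for interferon genes, since mouse interferon genes are nearly silent in these wells while the lowest of the 3 pair medians was log2 0.45. For the hypoxia genes a median of 18.3% of mouse reads would have to be miscounted, where C2C12 markers had a median of 0.0792% and at most 4.67% as many human as mouse reads, counting any expression by HEK cells as miscounted. Unequal depth is argued against by medians of log2 0.70, 0.40 and -0.24 in the interferon, immediate early and hypoxia lists after thinning, each larger in size than without it. The smaller share of C2C12 RNA in these wells, 16.5 percentage points, goes with the same line and cannot be told apart from the Notch1 line itself.

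The next pattern is the near silence of interferon genes in C2C12-Notch1 cells, and unequal depth is argued against by a median of log2 -5.73 after thinning. For Notch activation acting within the co-culture, the median in C2C12-control cells beside HEK-Jag1WT was -0.0712, but that line has less Notch1 and the co-culture lasted 6 h. In C2C12-Notch1 cells the median beside HEK-Jag1WT against HEK-control was 0.00651, so the silence was present beside HEK-control too. These medians, from single wells, argue only against activation by HEK-Jag1WT within that time. A difference of line or clone other than Notch1 cannot be told apart from Notch1, since each is represented by 1 line. Outside the list 41 further genes were called and had no reads in any C2C12-Notch1 well. Several, such as Oas3, Ifi27l2a, Iigp1, Trim30a and Gbp5, are known as interferon-inducible themselves. Others code for a cadherin (Cdh11), a Wnt ligand (Wnt5a) and a transcription factor (Sox2), with 1375, 72 and 58 reads over the C2C12-control wells. The absence of reads was thus not confined to the interferon programme. The 41 genes were not sorted by that programme, so their count does not show how far the difference reaches beyond it. Longer Notch1 expression in the line stays open and was not tested.

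The last pattern is the smaller C2C12 response to HEK-Jag1Ndr than to HEK-Jag1WT. A lower transcript level is argued against, since Jag1 reads per 1000000 human reads were 1.08 times as high in HEK-Jag1Ndr wells. Fewer HEK cells per C2C12 cell cannot be told apart, since Jag1 reads per 1000000 mouse reads were 0.867 times as high in the C2C12-control line and 0.795 times in the C2C12-Notch1 line, and cell counts at lysis were not used here. Other differences of the HEK lines, with 7843 human genes called between them, go with the ligand and cannot be told apart either. The mutant ligand itself stays open as the difference the design names.

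For both comparisons of C2C12 lines, the 10 splits of 6 wells into 3 and 3 are too few for a share under 0.05. The real split called 6569 mouse genes and the highest other split 0, and 1 of 10 splits gave as many. For human genes the real split called 658 and the highest other split 2, and again 1 of 10 gave as many. The other splits were fitted without a term for the C2C12 line, so the difference of the lines entered their spread. Their low counts are therefore no support for the real split.

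Some genes responded in opposite directions in the C2C12 lines, and these differences were not tested, since each response rests on a pair of single wells. With both counting intervals excluding 0, 28 of 8432 genes did so for HEK-Jag1WT and 78 of 9132 for HEK-Jag1Ndr, where counting error alone would give 10.5 and 11.4. Counting error leaves out variation between wells, so the excess does not show that the lines respond in opposite ways. To HEK-Jag1Ndr, Dnm3os differed by log2 -1.44 (-0.82 in C2C12-Notch1, 0.62 in C2C12-control), Fam193b by -0.96, Kdm4c by 0.81, Neat1 by -1.26, Notch1 by -0.61 (-0.10 against 0.50) and Ryr1 by -1.13. In C2C12-Notch1 cells Dnm3os, Fam193b and Neat1 were also lower beside HEK-Jag1WT, at -0.93, -1.02 and -1.51, while Notch1 was not, at 0.09. Both ligands were read against the same C2C12-Notch1 well with HEK-control. A shift of that well cannot be told apart from a response to HEK-Jag1Ndr. Notch1 reads in C2C12-Notch1 cells include the introduced gene, so they do not show the response of the cells' own Notch1. To HEK-Jag1WT, the Wnt antagonist gene Dkk2 differed by 1.39 (1.11 against -0.28) and Trex1 by 1.39 (0.87 against -0.52).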

How the results depend on the processing

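Thinning and leaving out Jag1 were chosen after the data were seen; the other alternatives were planned. Over the named genes, 8343 combinations of gene and setting stayed the same, 1411 lost the call in the same direction, 40 gained it and 21 changed direction. Staying the same meant keeping direction and side of the threshold. For single-well responses of Notch targets, which have no test, it meant staying within the counting interval. All medians of Notch targets in single wells moved by less than their interval under 4 alternatives. Counts within 1.5 times of the reported ones are not listed. Unless the construction of a setting explains it, the cause was not tested.

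The DESeq2 Wald test called 3585, 151, 6 and 41 mouse genes, in the order C2C12-Notch1, HEK-Jag1WT, HEK-Jag1Ndr, and HEK-Jag1Ndr against HEK-Jag1WT, and 71, 4267, 2995 and 4866 human genes. On log2(RPKM + 1) limma called 142, 2 and 5 mouse genes in the 3 HEK comparisons and 20 human genes between C2C12 partners, and on log2(RPKM + 0.1) it called 90, 2, 5 and 21. Without a low-count filter HEK-Jag1Ndr gave 91 mouse genes. Requiring 1.5-fold with glmTreat, a stricter test by construction, gave 1347, 48, 1 and 9 mouse genes and 8, 1286, 745 and 1680 human genes. With no term for the other line, whose effect then enters the spread, edgeR called 0, 0 and 0 mouse genes in the HEK comparisons and 0 human genes between C2C12 partners, with 168, 28, 79 and 50 at an unadjusted p under 0.05; DESeq2 and limma with the term gave the counts above. Thinned to the smallest well, which leaves fewer reads by construction, 4101, 198, 9 and 74 mouse genes and 338 human genes between C2C12 partners passed.

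Leaving out each well in turn gave 5382 to 5966, 303 to 580, 40 to 84 and 138 to 313 mouse genes, and 176 to 1428, 5047 to 7381, 4371 to 5965 and 6048 to 8313 human genes, in the same order. Where this leaves a HEK line with 1 well in the fit, that well is assumed to vary like the others. With an estimated correlation 0 mouse and 0 human lists passed camera, with 1 and 2 at an unadjusted p under 0.05, and fry passed 16 and 46.

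Directions that changed were mostly of interferon genes with few reads in C2C12-Notch1 wells. For HEK-Jag1Ndr, Usp18 became -0.30 in DESeq2 and -0.80 on log2(RPKM + 0.1), with -4.18 to 0.51 over wells left out, and Ifit3 became -0.83 on log2(RPKM + 0.1), with -3.73 to 0.56. Isg15 ranged from -0.19 to 0.43 and Gata3 from -0.0512 to 0.26. Against HEK-Jag1WT, Usp18 became -0.0024 in DESeq2 and -0.61 on log2(RPKM + 0.1), with -4.11 to 0.58, and Ifit3 ranged from -3.17 to 3.48. Hes1 ranged from -0.35 to 0.0476 and Myc from -0.0104 to 0.11. After thinning, Myc became -0.0574 and Lfng 0.25 against HEK-Jag1WT, Lfng 0.00595 for HEK-Jag1Ndr, and Gata3 -0.0232 for C2C12-Notch1. Every fit but the one without it has a term for the other line, which matches wells that share that line. The 2263529 mouse reads of the C2C12-Notch1 well with HEK-Jag1WT limit what low genes can show.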

Other observations

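The tests of zinc finger genes and of HNRNPA3P1 reads were chosen after the results were seen.

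The matricellular genes CYR61 and CTGF were higher in HEK-Jag1Ndr than in HEK-control cells, at log2 1.79 and 1.70 (edgeR adjusted p 7.42e-30 and 8.9e-29). Of the unfolded protein response list, the pseudokinase gene TRIB3 fell by 1.80 on the log2 scale in HEK-Jag1WT and by a log2 change of -1.27 in HEK-Jag1Ndr, and HERPUD1 by -1.45 in HEK-Jag1WT. The list as a whole was called in neither line, with 5 of 18 genes higher and 10 lower in HEK-Jag1WT (camera adjusted p 0.251) and 7 and 4 in HEK-Jag1Ndr (0.74). The neurofilament gene NEFL was higher in HEK-Jag1WT by 1.70 and lower in HEK-Jag1Ndr by -1.24. The growth gene MYC was lower in both, by -1.99 and -0.91. Between the Jag1 lines, the heat shock list had a median of 0.46 while fry gave the opposite direction, and HSPA1A, a near-identical copy of HSPA1B and therefore uncertain, was lower by -6.72 in HEK-Jag1Ndr.

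The HEK lines shared 1293 higher genes against HEK-control, where independent lists would share 764, and 1496 lower genes, against 939. Another 422 and 654 genes went opposite ways. The log2 changes correlated across genes with r = 0.283 and a covariance of 0.124, against 0.475 and 0.0207 in simulated unchanged groups sharing the HEK-control wells. Part of the excess may come from those shared wells.

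Zinc finger genes named ZNF were frequent among genes at least 4-fold lower in the Jag1 lines. In HEK-Jag1WT they made up 28 of 188 such genes, 14.9% against 3.28% of tested genes, a Fisher odds ratio of 5.44 (3.46 to 8.27, exact p 1.79e-11). In HEK-Jag1Ndr they made up 26 of 65, 40%, an odds ratio of 20.8 (12.0 to 35.4, exact p 3.89e-22). Genes at least 4-fold higher held 3 of 52 and 0 of 60. Of these lower zinc finger genes 21 were the same in both lines, and both comparisons use the same HEK-control wells. The hypothesis tested was only that such genes are over-represented among the lower ones, and it was found and tested on the same data. Why they differ was not tested, a higher level in HEK-control alone is not excluded, and genes of a cluster are not independent.

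HNRNPA3P1, lower in the human table beside C2C12-Notch1, had reads in proportion to mouse reads, with the highest well 1.37 times the lowest per 1000000 mouse reads and 2.83 times per 1000000 human reads. This is consistent with mouse reads counted on this pseudogene. HLA-L had 62, 69 and 119 reads in the C2C12-control wells and 40, 14 and 17 in the C2C12-Notch1 wells with HEK-control, HEK-Jag1WT and HEK-Jag1Ndr.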
